A study of Mus musculus with 15 samples.

How the data were processed

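RNA of 5 mouse cholangiocarcinoma cell lines, 3 libraries each, was sequenced as stranded, poly(A)-selected libraries, per the labels. The deposited values are raw counts of reads per gene, 1 table per library, which the authors made with featureCounts 2.0.6 on exons grouped by gene, reverse-stranded, with the GENCODE M38 annotation, per the file headers. Reads were aligned with STAR 2.7.11b to GRCm39 after quality control with FastQC 0.12.1, per the submitters' processing notes, which also name edgeR and limma. The command, per the file headers, counted each mate of a pair as a read, and 69.88 to 74.45% of the genes with 1 to 10 counts in a library had an even count, so counts are close to 2 times the number of fragments. Coordinates are those of the files, in GRCm39. Gene symbols were joined by gene identifier from an annotation of the earlier build GRCm38, which was used for symbols alone, and 51486 of 78275 identifiers got one.

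Correlations between libraries and principal components used log2 CPM with a prior count of 2. Each library was assigned to its cell line as labelled. The labels give 1 batch for all libraries. Genes were filtered with filterByExpr by line (minimum count 10, minimum total 15), which left 18759, and libraries were scaled by TMM. All 15 libraries went into 1 edgeR 4.0.16 quasi-likelihood fit with a coefficient per line (R 4.3.3), and F-tests were adjusted by Benjamini-Hochberg with a threshold of 0.05. Each resistant line was compared with its parent, KPCh972-RR with KPCh993-RR and hKP with KPCh, and the change in hKP117-RR was set against the mean change in the KPCh lines. A gene was said to rise, fall or change only where its adjusted p passed. CPM were computed from the TMM-scaled library sizes, and errors are SDs over the 3 libraries. Library totals ran from 33851194 to 43021763 reads with a median of 36747057, and 22790 to 25437 genes had at least 1 read in a library.

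The floor was 6 reads, which is 3 read pairs, over the libraries of a group. A fold against a group with no read is a lower bound against that floor, and where a group had 1 to 6 reads the ratio has a 95% Poisson interval. Intervals and floors cover counting error only.

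A set of 41 gene lists had 891 entries, and 890 entries were matched (Muc6 was not). Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and adjusted over the lists of a comparison. Erythroid and platelet markers had fewer than 3 tested genes and were not tested. The estimated inter-gene correlation and fry, which tests a list without comparing it with other genes, were alternatives. The lists with a call in a comparison were epithelial, fibroblast and stellate, biliary, gastrointestinal and squamous, hepatocyte, mesenchymal, stem and progenitor, WNT and Notch, TGF-beta, interferon, MHC class I, NF-kB and cytokines, ATF4 and unfolded protein response, MYC targets, E2F and replication, mitosis, oxidative phosphorylation, mitochondrially encoded, autophagy and lysosome, cholesterol biosynthesis, integrins and extracellular matrix, and receptor tyrosine kinases. The lists without a call in any comparison were apoptosis regulators, cell cycle inhibitors and p53 targets, cytosolic ribosomal proteins, drug efflux transporters, endothelial markers, fatty acid oxidation, fatty acid synthesis and uptake, glycolysis, growth factor ligands, housekeeping controls, hypoxia, immune cell markers, MAPK output, NRF2 targets, the RAF-MEK-ERK and PI3K-AKT cascade, RAS family and exchange factors, replication-dependent histones, and YAP/TAZ targets. Chromosomes were tested as sets with camera and an estimated correlation.

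The lists, the comparisons, the tests and the rule for naming genes were fixed before the data were examined. The rule took the 8 largest rises and 8 largest falls of each resistant line against its parent among genes with a symbol that is not a predicted or clone name, a mean of at least 10 CPM in the higher group and no overlap between the groups, which chance gives in 10% of splits of 3 against 3. It took 6 and 6 for the other comparisons of lines, 8 and 8 of the genes changed the same way in all 3 resistant lines by their smallest change, up to 4 members of each list described, and always Kras, Hras, Nras, Myc, Ppia, Egfr, Dusp6, Spry4, Etv4, Etv5, Trp53, Yap1, Cdh1 and Vim.

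The labels give no pairing, so pairing by replicate number was checked in the data. In KPCh972-RR against KPCh and in KPCh972-RR against KPCh993-RR the deviations of same-numbered libraries from their line's mean correlated, across genes, at 0.1257 to 0.1969 and at 0.1114 to 0.2297, above the limit of 0.1 in every pair, so blocked values are given there where a call changed. Alternatives were RLE, upper-quartile and library-size scaling, no filter or a stricter filter, DESeq2 1.42.0, limma-voom, the replicate block, the 6 libraries of a comparison alone, each library left out in turn, a 2-fold threshold, for chromosomes the preset correlation and genes of at least 5 CPM, and, chosen after seeing the data, halved counts and lists without KPCh972-RR replicate 1.

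The fit was tested on simulated data with 200 genes changed by known folds. Of genes changed 2-fold it recovered 47.8% for hKP117-RR against hKP, 43.2% for KPCh972-RR against KPCh and 46.9% for KPCh993-RR against KPCh, and of genes changed 1.5-fold 11.8, 8.7 and 11.6%, with 3, 5 and 4 false calls. For the background difference it recovered 14.1% of genes changed 2-fold. In the data 5106 to 8426 genes were called in the comparisons, so the Benjamini-Hochberg cut was looser there than in the simulation. These shares may therefore understate recovery in the data. Likeness between the KPCh lines, which share controls, was set against 20 simulations without an effect. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.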

Results

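Messenger RNA of 5 mouse cholangiocarcinoma (bile duct cancer) cell lines was measured by stranded, poly(A)-selected RNA sequencing, with 3 libraries per line and 15 in all. The lines hKP and KPCh were the untreated parental lines. The lines hKP117-RR, KPCh972-RR and KPCh993-RR were resistant lines generated in vivo, and their labels name RMC-7977, an inhibitor that binds the active, GTP-bound state of RAS proteins in a complex with cyclophilin A. The labelled concentration was 200 nM for hKP117-RR, 2 µM for KPCh972-RR and 100 nM for KPCh993-RR, so the drug, its concentration, resistance and the cell line cannot be separated. The genotype label names a TP53 allele whose number rises from library to library, and all lines were treated as having the same TP53 genotype. The Trp53 values below therefore cannot be tied to a genotype. The labels do not say whether the 3 libraries of a line came from separate cultures. Every p-value of a single gene below therefore measures the spread between these libraries. P-values of lists and chromosome sets rest on the same libraries but measure something else. They come from camera, which compares the members of a set with the other genes at a preset or estimated correlation. The total count per library ran from 33851194 to 43021763 reads, and each mate of a read pair was counted as a read. Of the 78275 genes in each file, 18759 passed the filter on low counts and were tested. Across genes, log2 CPM (counts scaled to library size) correlated at 0.968 to 0.988 between replicates of a line and at 0.831 to 0.941 between lines. The lowest values within a line were those of KPCh972-RR replicate 1 with replicates 2 and 3 (0.9694 and 0.9677), which correlated with each other at 0.9809.

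**Figure D1:**
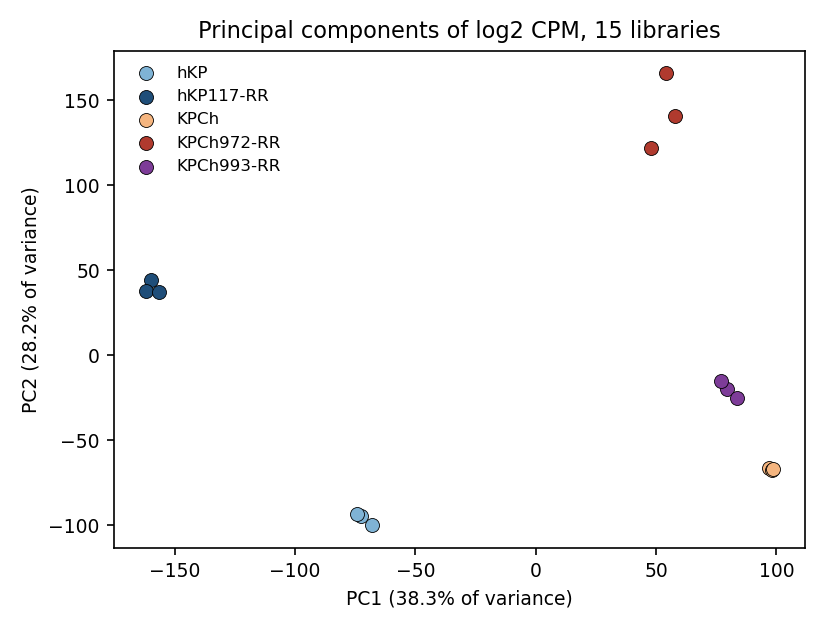
Principal components 1 and 2 of log2 CPM over the tested genes, with 1 point per library and 1 colour per cell line. Component 1, with 38.3% of the variance, placed the hKP lines on the left and the KPCh lines on the right, and component 2 held 28.2%.

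The comparison of hKP117-RR with hKP asked which genes and pathways were altered in the resistant line of the hKP background. Most epithelial genes fell in hKP117-RR, while most interferon-response and cytokine genes of the lists rose. Cdh1 (ENSMUSG00000000303.14, GRCm39 chromosome 8, 107329983 to 107396878), which encodes the adhesion protein E-cadherin, fell from 142 ± 21.4 CPM in hKP to 0.0473 ± 0.0818 CPM in hKP117-RR (SD, n = 3 each), a 3110-fold difference with a counting interval of 886 to 12600. Mmp2 (ENSMUSG00000031740.9, chromosome 8, 93553919 to 93580048), a gelatinase that degrades matrix, was at 135 ± 16.7 CPM in hKP117-RR and had no read in hKP, which makes it at least 2540-fold higher. Col1a2 (ENSMUSG00000029661.17, chromosome 6, 4504814 to 4541544), a chain of type I collagen, rose from 0.894 ± 0.385 to 806 ± 54.8 CPM. In all, 7918 genes changed, 3636 upward and 4282 downward, and 4011 of them changed at least 2-fold.

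Among the 24 tested members of the epithelial list, 23 fell and none rose in hKP117-RR. Their median log2 fold change was -5.81, or -5.37 with the 11 members at the detection floor set to that floor (adjusted p = 1.87e-29, and adjusted p = 0.00391 with an estimated correlation). No read of St14, Tjp3 or Esrp1 was counted in hKP117-RR, and these genes were at least 140-fold, 131-fold and 79.0-fold lower than in hKP. Esrp1 encodes a splicing regulator of epithelial cells and Tjp3 a tight junction protein. Of 22 biliary genes 13 fell and 2 rose (adjusted p = 2.26e-07, and adjusted p = 0.126 with an estimated correlation), among them Prom1, a progenitor and bile duct marker that was at least 311-fold lower. Of 19 gastrointestinal and squamous lineage genes 13 fell and none rose (adjusted p = 6.45e-07, and adjusted p = 0.126 with an estimated correlation), with the endoderm factor Foxa2 at least 75.9-fold lower. Members of the WNT and Notch list fell in 13 of 23 cases and rose in none (adjusted p = 1.45e-05, and adjusted p = 0.126 with an estimated correlation), led by Notum with a log2 fold change of -8.48 and Rnf43 with -7.91, both of which encode WNT inhibitors. Of 14 stem and progenitor genes 8 fell and 1 rose (adjusted p = 0.0169, and adjusted p = 0.126 with an estimated correlation), and Sox2 was at least 42.1-fold lower.

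Interferon-response genes rose in hKP117-RR in 26 of 28 cases, with none lower and a median log2 fold change of 4.12 (adjusted p = 1.32e-10, and adjusted p = 0.432 with an estimated correlation). The levels differed widely between its replicates: Ifi44 was at 32.2, 54.5 and 5.16 CPM in replicates 1, 2 and 3, against 0.0178 ± 0.0308 CPM in hKP (SD, n = 3). Oas1a, a sensor of double-stranded RNA, rose by a log2 fold change of 7.53. In the MHC class I list 9 of 18 genes rose and 1 fell (adjusted p = 0.00412, and adjusted p = 0.8 with an estimated correlation), and the immunoproteasome subunit Psmb8 went from 3.70 ± 0.619 to 33.98 ± 12.6 CPM. Of 25 NF-kB and cytokine genes 17 rose and 1 fell (adjusted p = 1.45e-05, and adjusted p = 0.284 with an estimated correlation), including the chemokines Ccl7 (log2 fold change 4.82), Ccl2 (4.31) and Ccl5 (3.84). The mesenchymal list had 14 of 28 members higher and 5 lower (adjusted p = 0.000446, and adjusted p = 0.524 with an estimated correlation), and Col1a1 rose from 60.9 ± 10.6 to 1864 ± 161 CPM. Of 9 fibroblast markers 6 rose and none fell (adjusted p = 0.0243, and adjusted p = 0.293 with an estimated correlation), with decorin (Dcn) at least 44.2-fold higher. MYC targets were higher in 18 of 28 cases and lower in 1 (adjusted p = 1.08e-05, and adjusted p = 0.8 with an estimated correlation), by a median of 0.61. The ATF4 and unfolded protein response list had 13 of 25 members higher and none lower (adjusted p = 0.000364, and adjusted p = 0.555 with an estimated correlation), with Chac1, a glutathione-degrading enzyme, at a log2 fold change of 2.77.

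The 8 largest rises in hKP117-RR were Mmp2, Fendrr, Fyb2, Foxf1, Srpx2, Ifi44, Col1a2 and Il1rl1. Fendrr and Foxf1 lie next to each other on chromosome 8, and Foxf1 encodes a transcription factor of mesenchyme. Il1rl1, the receptor of interleukin 33, rose from 1.19 ± 0.309 to 948 ± 98.7 CPM. The 8 largest falls were Sel1l3, Fgfr4, Stxbp5, Map3k21, Klhl1, Prom1, Cdhr5 and Ell2, none of which had a read in hKP117-RR, so that each was at least 292-fold lower. The receptor tyrosine kinase list moved both ways, with 9 of 24 members higher and 8 lower (adjusted p = 0.996). The growth factor receptor Fgfr4 was at least 438-fold lower, Erbb3 was 244-fold lower with a counting interval of 83.4 to 1180, and the collagen receptor Ddr2 rose from 1.14 ± 0.360 to 409 ± 24.5 CPM. Kras fell by 0.67 on the log2 scale (adjusted p = 0.000109) and Egfr fell by 1.24 (adjusted p = 0.0022), while Trp53 rose by 0.71 (adjusted p = 0.00144). Myc rose by 0.48 (adjusted p = 0.0267), and this call ended without hKP117-RR replicate 2 (adjusted p = 0.144), hKP replicate 1 (0.119) or hKP replicate 2 (0.0586), with a range of 0.000426 to 0.144 over 25 alternatives. Nras fell by 0.25 (adjusted p = 0.0258), a call that leaving out any 1 of the 6 libraries ended (adjusted p from 0.0532 to 0.0792, and from 0.0064 to 0.208 over 25 alternatives). Hras had a log2 fold change of -0.21 (adjusted p = 0.0694, or 0.043 without hKP replicate 2). For Ppia, which encodes cyclophilin A, it was 0.15 (0.111, or 0.0362 with upper-quartile scaling), for Yap1 0.10 (0.443) and for Vim -0.12 (0.519).

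In the list of MAPK output, which holds genes transcribed in response to ERK signalling, 3 of 20 members rose and 3 fell in hKP117-RR (adjusted p = 0.996). Fosl1 rose by a log2 fold change of 2.10 and Spry2 fell by 1.43. Dusp6, Spry4, Etv5 and Etv4 had log2 fold changes of -0.42, -1.50, -0.95 and -0.08 that did not pass (adjusted p = 0.416, 0.235, 0.358 and 0.951). The first 3 passed when KPCh972-RR replicate 1, a library outside this comparison, was left out of the common fit (adjusted p = 0.0238, 0.00092 and 7.72e-05), and when the 6 libraries compared were fitted alone (adjusted p = 0.00616, 8.17e-05 and 5.87e-05). The list without that replicate, tested after the data were seen, had 5 members higher and 8 lower (adjusted p = 0.593). Over 25 alternatives the adjusted p ran from 0.00616 to 0.628 for Dusp6 and from 5.25e-15 to 0.395 for Spry4, and over 24, without DESeq2, which gave none, from 6.83e-08 to 0.511 for Etv5.

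The comparison of KPCh972-RR with KPCh asked the same question in the KPCh background. The epithelial programme was lost in KPCh972-RR too, the type I collagen gene Col1a2 rose from near absence to more than 1000 CPM in each replicate, and ERK output genes were low in replicates 2 and 3. Cdh1 fell from 526 ± 51.5 to 5.13 ± 6.39 CPM (SD, n = 3 each) and Krt7, a keratin of bile duct epithelium, from 1230 ± 225 to 0.545 ± 0.369 CPM. Col1a2 rose from 0.0181 ± 0.0313 CPM, which is 2 reads in 3 libraries, to 3060 ± 1780 CPM, with 1034, 4400 and 3745 CPM in replicates 1, 2 and 3. A total of 8426 genes changed, 3866 upward and 4560 downward, of which 4470 changed at least 2-fold.

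All 24 tested epithelial genes fell in KPCh972-RR, with a median log2 fold change of -6.76, or -6.46 with 7 members set to the floor (adjusted p = 5.99e-41, and adjusted p = 7.26e-05 with an estimated correlation). Esrp1 had no read in the line and was at least 999-fold lower, and the tight junction gene Cldn3 was 5440-fold lower with a counting interval of 977 to 215000. Of 22 biliary genes 13 fell and 3 rose (adjusted p = 2.25e-09, and adjusted p = 0.0919 with an estimated correlation). Of 19 gastrointestinal and squamous genes 14 fell and 1 rose (adjusted p = 1.11e-05, and adjusted p = 0.0919 with an estimated correlation), among them the mucin Muc5ac and the intestinal factor Cdx2 with log2 fold changes of -8.42 and -8.04. Of 8 tested hepatocyte genes 5 fell and none rose (adjusted p = 0.0130, and adjusted p = 0.172 with an estimated correlation), including Hnf4a with -6.42. The WNT and Notch list had 14 of 23 members lower and 3 higher (adjusted p = 0.00834, and adjusted p = 0.365 with an estimated correlation). In the list of integrins and extracellular matrix 12 of 28 fell and 7 rose (adjusted p = 0.0122, and adjusted p = 0.555 with an estimated correlation), a call that ended with the replicate block (adjusted p = 0.0591). Its largest falls were Itgb4 (-7.71) and Lama3 (-7.35), which encode parts of the hemidesmosome anchorage of epithelium, and the basement membrane collagens Col4a1 (-7.28) and Col4a2 (-6.69).

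Mesenchymal genes rose in 19 of 28 cases and fell in 1 (adjusted p = 3.16e-06, and adjusted p = 0.357 with an estimated correlation), with a median of 1.32, or 1.53 with 5 members set to the floor and 1 without a fold left out. Of the markers of contractile and matrix-forming cells, Postn was 876-fold higher with a counting interval of 300 to 4250 and Tagln had a log2 fold change of 8.88, and Col1a1 rose from 2.02 ± 0.546 to 373 ± 301 CPM. Vim rose by 0.39 (adjusted p = 0.0345). This call ended without KPCh972-RR replicate 1 (adjusted p = 0.188), KPCh replicate 2 (0.107) or 3 (0.13), or hKP117-RR replicate 2 (0.0613) or 3 (0.0577). It also ended with library-size scaling (0.0575) and with the 6 libraries compared fitted alone (0.0988). The adjusted p of Vim ran from 0.000946 to 0.188 over 25 alternatives. Genes of oxidative phosphorylation rose in 18 of 25 cases by a median of 0.38 (adjusted p = 0.000278, and adjusted p = 0.472 with an estimated correlation), with none lower. The ATF4 and unfolded protein response list rose in 14 of 25 cases, with none lower (adjusted p = 0.00325, and adjusted p = 0.532 with an estimated correlation), led by Herpud1 (2.15) and Ddit3 (1.98). Autophagy and lysosome genes were higher in 12 of 28 cases and lower in 4 (adjusted p = 0.0057, and adjusted p = 0.357 with an estimated correlation), and Mitf, a transcription factor that controls lysosomal genes, rose by 3.74. Of 28 E2F and replication genes 16 rose and 2 fell (adjusted p = 0.0130, and adjusted p = 0.683 with an estimated correlation), and of 28 MYC targets 11 rose and 1 fell (adjusted p = 0.0264, and adjusted p = 0.846 with an estimated correlation). Both of these calls ended without KPCh972-RR replicate 1 (adjusted p = 0.0891 and 0.130). MHC class I genes were higher in 8 of 18 cases and lower in 2 (adjusted p = 0.0673, or 0.0480 with the replicate block and 0.00479 without replicate 1). The interferon, NF-kB and cytokine, and fibroblast lists had medians of 0.78, 0.16 and 2.153 and did not pass. Without replicate 1, a choice made after the data were seen, they passed with medians of 0.96, 0.316 and 2.305 (adjusted p = 0.0263, 0.00926 and 0.0192). With library-size scaling the interferon and MHC class I lists passed (adjusted p = 0.0485 each).

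MAPK output genes depended on the replicate of KPCh972-RR. Over all 3 replicates 10 of 20 members fell and 2 rose, by a median of -0.80 (adjusted p = 0.160). Without replicate 1, a choice made after the data were seen, 15 fell and 2 rose, by a median of -2.03 (adjusted p = 5.49e-09). Dusp6, an ERK phosphatase, was at 90.9, 26.2 and 20.7 CPM in replicates 1, 2 and 3, against 146 ± 18.1 CPM in KPCh. Etv4, an ERK-induced transcription factor, was at 86.0, 9.95 and 3.83 CPM against 153 ± 15.9 CPM. Etv5 was at 21.6, 1.00 and 0.406 CPM against 48.3 ± 2.51 CPM, and Spry4, a feedback inhibitor of receptor signalling, at 46.2, 1.41 and 0.580 CPM against 27.5 ± 7.07 CPM. Dusp6, Etv4 and Etv5 passed the test with log2 fold changes of -1.67, -2.20 and -2.63 (adjusted p = 0.00319, 0.0207 and 0.0188). The call for Etv4 ended without replicate 2 (adjusted p = 0.0666), and over 24 alternatives its adjusted p ran from 5.98e-57 to 0.12. That of Etv5 ran from 2.43e-52 to 0.123, and both calls ended when the 6 libraries of the comparison were fitted alone (adjusted p = 0.12 and 0.123). DESeq2 gave no adjusted p for either gene (log2 fold changes of -2.21 and -2.67), so they were not called there. Spry4 did not pass in the main fit (-0.76, adjusted p = 0.553) and did without replicate 1 (-4.81, adjusted p = 7.34e-07). With all libraries it passed under limma-voom (-2.74, adjusted p = 0.0234) and without the low-count filter (-0.76, adjusted p = 0.000131). Spry1 moved the other way and rose from 17.7 ± 4.59 to 323 ± 144 CPM.

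**Figure D2:**
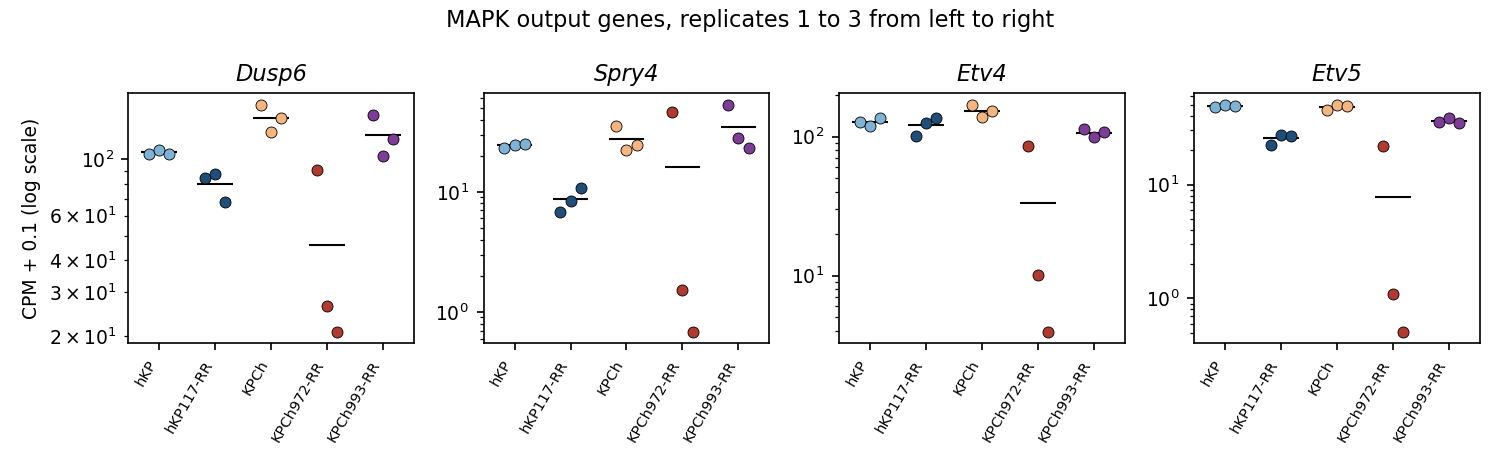
CPM plus 0.1, on a log scale, of 4 MAPK output genes in each library, with replicates 1 to 3 of each line from left to right and a bar at the line's mean. In KPCh972-RR, Dusp6 was at 90.9 CPM in replicate 1 and at 26.2 and 20.7 CPM in replicates 2 and 3.

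The largest rises in KPCh972-RR were Col1a2, Cpq, Igfbp2, Alkal1, Ccdc80, Xirp2, Gdnf and Tenm3. Gdnf, a ligand of the RET receptor complex, rose from 0.0736 ± 0.0638 to 113 ± 60.4 CPM, while the receptor gene Ret had no read in KPCh972-RR and was at least 543-fold lower. The other largest falls were Peg3, Esrp1, Myh14, Eif2s3y, Acan, Map3k9 and Klrc1. The paternally expressed imprinted gene Peg3 (ENSMUSG00000002265.18, chromosome 7, 6706891 to 6733430) went from 171 ± 27.7 CPM to no read, at least 3200-fold lower. Of 24 receptor tyrosine kinases 7 rose and 11 fell (adjusted p = 0.160), with Ddr2 up from 0.663 ± 0.435 to 282 ± 107 CPM. Myc rose by 0.69 (adjusted p = 0.00293) and Nras by 0.41 (adjusted p = 0.00124), while Kras had a log2 fold change of -0.18 (adjusted p = 0.176). Trp53 fell by 0.41 (adjusted p = 0.0349), and leaving out KPCh972-RR replicate 2 or 3 or KPCh replicate 1 or 2 ended this call (adjusted p from 0.0718 to 0.125, 0.0768 with the 6 libraries compared fitted alone, and from 0.00879 to 0.195 over 25 alternatives). Hras (-0.03, adjusted p = 0.781), Ppia (0.07, 0.454) and Yap1 (-0.10, 0.448) did not pass, nor did Egfr (0.32, 0.359). Egfr passed without KPCh972-RR replicate 1 (0.62, adjusted p = 0.00622) and without the low-count filter (0.32, adjusted p = 0.0469).

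**Figure D3:**
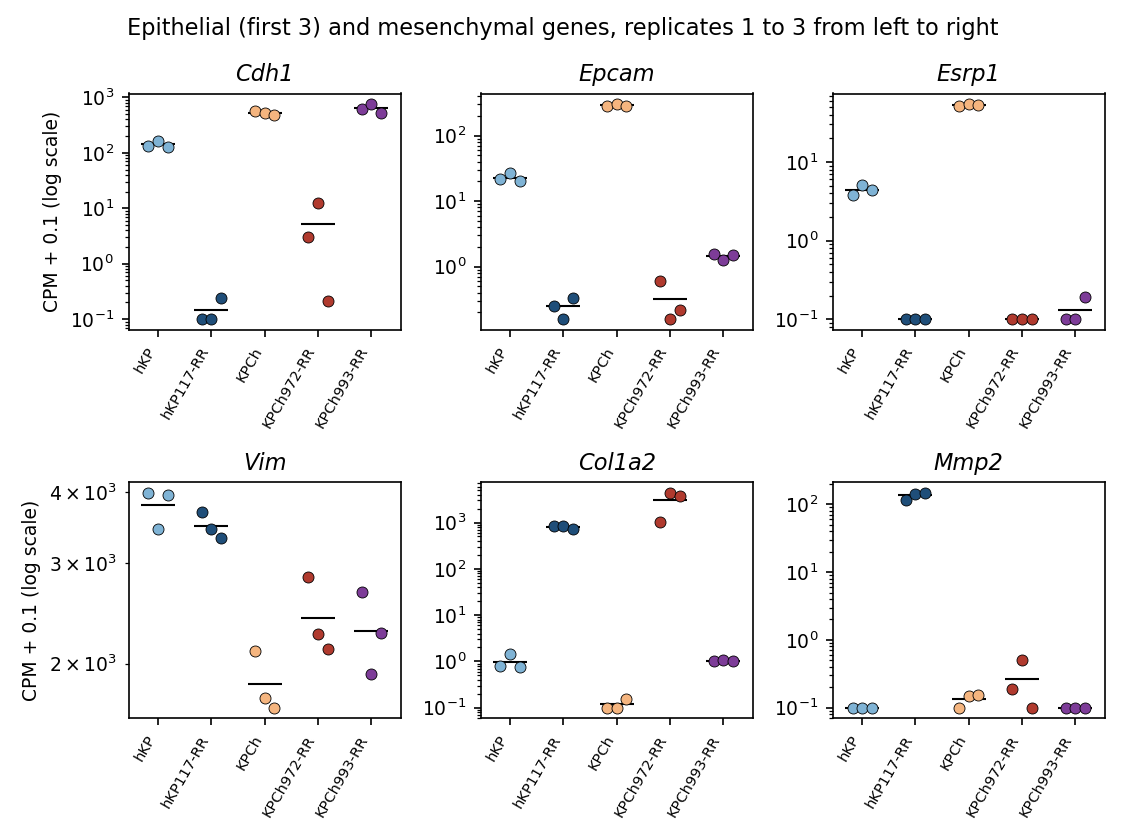
CPM plus 0.1, on a log scale, of 3 epithelial genes (Cdh1, Epcam, Esrp1) and 3 mesenchymal genes (Vim, Col1a2, Mmp2) in each library, with replicates 1 to 3 from left to right and a bar at the line's mean. Mean Cdh1 was 0.0473 CPM in hKP117-RR, 5.13 CPM in KPCh972-RR and 632 CPM in KPCh993-RR, and Mmp2 was at 135 CPM in hKP117-RR.

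KPCh993-RR, the other resistant line of the KPCh background, kept Cdh1 and lost other epithelial genes, and a block of genes at the start of chromosome 5 that holds the drug efflux pumps Abcb1a and Abcb1b was higher by medians of 8.5-fold and 20.6-fold in its 2 parts. Abcb1b (ENSMUSG00000028970.10, GRCm39 chromosome 5, 8848147 to 8916315) rose from 134 ± 11.7 to 2882 ± 252 CPM (SD, n = 3 each), a log2 fold change of 4.43 (adjusted p = 4.81e-09). Abcb1a (ENSMUSG00000040584.9, chromosome 5, 8710077 to 8798575) rose from 35.9 ± 1.49 to 776 ± 74.9 CPM, and the phospholipid pump Abcb4 (ENSMUSG00000042476.13, chromosome 5, 8943717 to 9009231) from 1.93 ± 0.127 to 46.3 ± 17.6 CPM. These pumps are close paralogs, so reads can be shared between them. In KPCh993-RR 5106 genes changed, 2396 upward and 2710 downward, and 2209 of them changed at least 2-fold.

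The block was singled out after its values were seen. Its bounds were set by genes at least 2-fold higher, and the 1 gene between its parts was set apart by its fold. Counts of genes that were 2-fold higher in it follow in part from this choice. Its first part, from 3320039 to 5799326 on chromosome 5, held 30 genes at 1 CPM or more in KPCh or KPCh993-RR, all of them at least 2-fold higher, with a median log2 fold change of 3.09 (8.5-fold). Cdk6, a kinase that drives entry into the cell cycle, lies there and rose from 298 to 2394 CPM. The second part, from 8087294 to 9211776, held 14 genes, all at least 2-fold higher, with a median of 4.36 (20.6-fold). Between them the predicted gene Gm15459 had a log2 fold change of -0.12. The next 20 genes of the chromosome at 5 CPM or more in KPCh, from 13175381 to 23639396, had a median of -0.49 and none was 2-fold higher. Over the whole block the median was -0.03 in KPCh972-RR and 0.55 in hKP117-RR. Among genes at 5 CPM or more in either line, ordered along the chromosomes, 25 neighbours in a row were at least 2-fold higher in KPCh993-RR, while the longest run in 1000 shuffles of gene order was 4. In the drug efflux list as a whole 3 of 13 genes rose and 5 fell (adjusted p = 0.626). In hKP117-RR Abcb1b rose from 56.8 ± 13.0 to 252 ± 25.9 CPM and Abcg2 fell from 15.4 ± 0.868 to 0.252 ± 0.169 CPM, with 3 of 13 list members higher and 7 lower (adjusted p = 0.145, or 0.0395 without KPCh972-RR replicate 1). In KPCh972-RR Abca1, a cholesterol exporter, rose by a log2 fold change of 4.92, Abcg2 rose from 12.4 ± 1.48 to 56.3 ± 26.5 CPM and Abcb1a fell by 2.33, with 3 of 13 members higher and 5 lower (adjusted p = 0.541). The values of Abcb1b in hKP117-RR and of Abcg2 in KPCh972-RR were chosen after they were seen.

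**Figure D4:**
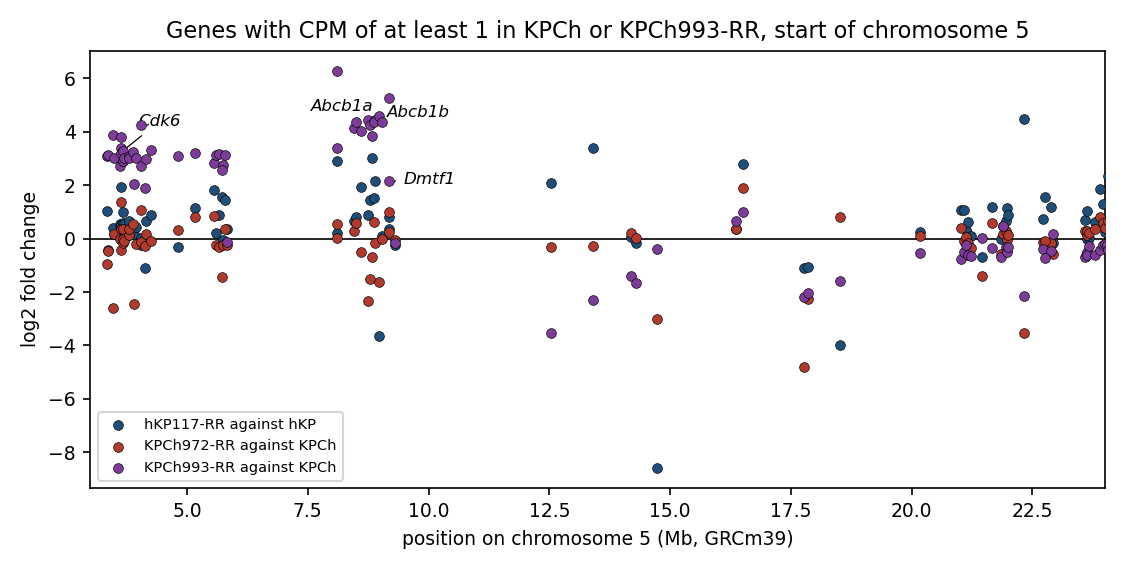
Log2 fold change of each gene, with 1 point per gene and comparison, against the middle of the gene on chromosome 5 in megabases (GRCm39), for the 3 resistant lines against their parents. In KPCh993-RR the median was 3.09 in the first part of the block and 4.36 in the second, and -0.49 over the next 20 genes at 5 CPM or more.

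Of the 24 epithelial genes 15 fell and none rose in KPCh993-RR, by a median of -2.99 (adjusted p = 5.48e-32, and adjusted p = 0.00303 with an estimated correlation). Cdh1 was at 632 ± 115 CPM against 526 ± 51.5 CPM and did not pass (adjusted p = 0.807). Esrp1 was 1520-fold lower with a counting interval of 422 to 12600, and the epithelial factor Grhl2 and the tight junction gene Cldn4 had log2 fold changes of -8.75 and -7.77. Of 22 biliary genes 8 fell and 2 rose (adjusted p = 3.94e-05, and adjusted p = 0.480 with an estimated correlation), among them Tacstd2, a surface glycoprotein of epithelial tumours that was at least 695-fold lower, and Krt7 with -5.5. The receptor tyrosine kinase list had 11 of 24 members lower and none higher (adjusted p = 0.0013, and adjusted p = 0.480 with an estimated correlation), led by Ephb2, 506-fold lower with a counting interval of 90.7 to 20000, and by Ret and Epha1 with log2 fold changes of -7.54 and -6.35. In the list of integrins and extracellular matrix 10 of 28 fell and 2 rose (adjusted p = 0.00814, and adjusted p = 0.847 with an estimated correlation), including Lama3 with -8.60. The mesenchymal list had 7 of 28 members higher and 2 lower (adjusted p = 0.0510, and from 0.0475 to 0.0487 with the 3 other scalings), and Col1a2 rose to no more than 0.942 ± 0.0334 CPM.

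E2F and replication genes rose in 19 of 28 cases and fell in 2 in KPCh993-RR (adjusted p = 3.48e-06, and adjusted p = 0.480 with an estimated correlation), by a median of 0.46, with Mcm10, a replication initiation factor, up from 75.1 ± 3.24 to 146 ± 3.83 CPM. Interferon-response genes rose in 10 of 28 cases and fell in none (adjusted p = 4.38e-05, and adjusted p = 0.847 with an estimated correlation), from low levels: Ifit1 was at 0.530 ± 0.191 CPM. Of 18 MHC class I genes 9 rose and none fell (adjusted p = 0.0035, and adjusted p = 0.898 with an estimated correlation), with the peptide transporter Tap2 up from 0.363 ± 0.151 to 4.60 ± 1.38 CPM. Of 25 NF-kB and cytokine genes 11 rose and 1 fell (adjusted p = 0.0127, and adjusted p = 0.847 with an estimated correlation), with the adhesion molecule Vcam1 up from 62.8 ± 23.3 to 397 ± 180 CPM. Genes of oxidative phosphorylation rose in 8 of 25 cases and fell in none (adjusted p = 0.0145, and adjusted p = 0.847 with an estimated correlation), by a median of 0.19. Of 20 MAPK output genes 1 rose and 1 fell (adjusted p = 0.844), and Dusp6, Etv4, Etv5 and Spry4 did not pass (adjusted p from 0.626 to 0.837). Without KPCh972-RR replicate 1 in the common fit Etv5 passed, with a log2 fold change of -0.42 (adjusted p = 0.0376). With the 6 libraries compared fitted alone Etv5 and Etv4 did (-0.42 and -0.53, adjusted p = 0.0114 and 0.0051). Etv4 also passed without the low-count filter (adjusted p = 0.00105). Kras fell by 0.46 (adjusted p = 0.00396). Hras (0.02, adjusted p = 0.915), Myc (0.20, 0.396), Egfr (-0.27, 0.518), Trp53 (-0.31, 0.14), Yap1 (-0.04, 0.804) and Vim (0.31, 0.116) did not pass. Nor did Nras (0.19, adjusted p = 0.115) and Ppia (0.13, 0.213), which passed without KPCh993-RR replicate 1 (0.0212 and 0.0442). The largest rises were Runx3, Hoxb6, Hoxb3, Igfbp5, Ptgs2os2, Adh7, Avil and Ecscr, and Hoxb6, a homeobox factor, went from 0.0431 ± 0.0387 to 19.1 ± 3.18 CPM. The largest falls were Cdcp1, Ppp2r2c, Cldn6, Eif2s3y, Tacstd2, Ddx3y, Ap1m2 and Peg3.

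Genes that changed the same way in all 3 resistant lines numbered 1192, with 471 higher and 721 lower. Independent lists of the same sizes would give 95.7 and 150.4. That baseline does not allow for the controls that KPCh972-RR and KPCh993-RR share, or for chromosomes that shifted as sets in both lines. The excess over it is therefore not a measure of a common response. The chemokine Ccl2 rose in each line, by log2 fold changes of 4.31 in hKP117-RR, 3.56 in KPCh972-RR and 3.67 in KPCh993-RR, to 210 ± 28.2, 175 ± 98.1 and 189 ± 54.0 CPM (SD, n = 3 each). Ranked by their smallest change over the lines, the other leading shared rises were Trps1, Aldh1l2, Ggt7, Zfpm2, Six1, Ly75 and Glipr1. Aldh1l2, an enzyme of mitochondrial folate metabolism, rose by 2.47, 6.30 and 4.46, and the homeobox gene Six1 by 7.20, 2.16 and 1.96. By the same ranking the leading shared falls were Prom1, Padi4, Cldn4, Cdcp1, Epcam, Map3k21, Cldn3 and Krt7. Epcam (ENSMUSG00000045394.10, chromosome 17, 87943407 to 87958557), an epithelial adhesion molecule, fell by 7.25, 10.19 and 7.76, and Krt7 by 5.42, 11.17 and 5.5. At least 2-fold in each line were 123 genes higher and 382 lower.

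**Figure D5:**
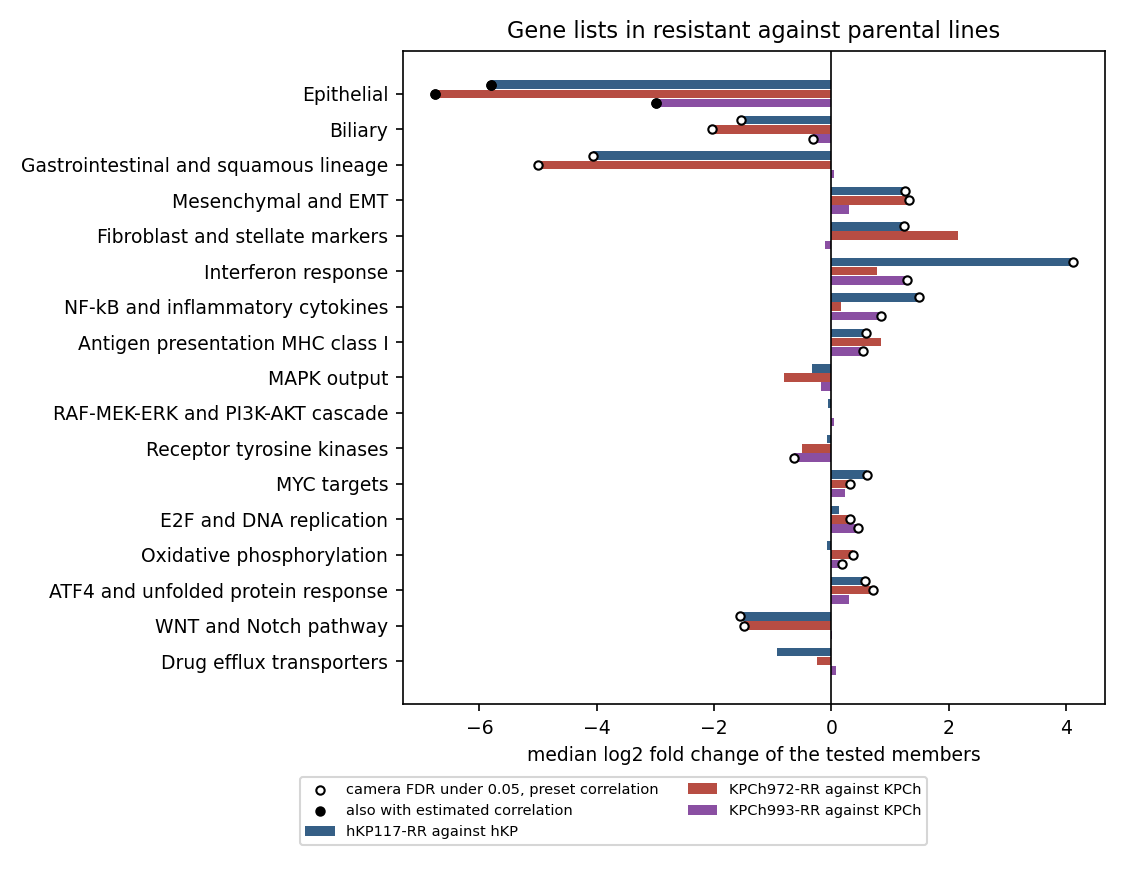
Median log2 fold change of the tested members of 17 gene lists in each resistant line against its parental line, with open circles where camera passed with the preset correlation and filled circles where it passed with the estimated one too. The epithelial list had medians of -5.81, -6.76 and -2.99 and was the one list with filled circles.

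KPCh972-RR and KPCh993-RR share their KPCh controls, so part of any likeness between them is built in. They had 1337 rises and 1601 falls in common, against 493.8 and 658.8 for independent lists, and 485 genes changed in opposite directions. The correlation of the log2 fold changes over genes was 0.499, and 20 simulations with no effect gave a mean of 0.502. A shared control gives a correlation of about that size by itself, so this match does not tell how much likeness is built in. The covariance was 1.68 against 0.115 simulated, so noise in the shared controls, as simulated, made up a small part of it. The simulations had 0 shared rises and 0 shared falls. Since they called hardly any gene, they do not tell how many shared calls the controls add. The pairs that share no library had fewer calls in common relative to independent lists: hKP117-RR and KPCh972-RR shared 1381 rises and 1957 falls, against 749.3 and 1040.9, with 1071 genes opposite. For hKP117-RR and KPCh993-RR these counts were 703 and 944, against 464.4 and 618.6, with 1133 opposite.

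The direct comparison of KPCh972-RR with KPCh993-RR tested where the resistant lines of one parent differed. KPCh972-RR was the more mesenchymal of the pair and KPCh993-RR the more epithelial: Cdh1 was at 5.13 ± 6.39 against 632 ± 115 CPM, the simple epithelial keratin Krt8 at 14.6 ± 15.5 against 1588 ± 76.1 CPM, and Col1a2 at 3060 ± 1780 against 0.942 ± 0.0334 CPM (SD, n = 3 each). A total of 7325 genes differed, 3408 higher and 3917 lower in KPCh972-RR. Of 24 epithelial genes 17 were lower and none higher, by a median of -4.27, or -2.58 with 6 members set to the floor and 1 without a fold left out (adjusted p = 5.14e-11, and adjusted p = 0.0281 with an estimated correlation). Gastrointestinal and squamous genes were lower in 15 of 19 cases and higher in 2 (adjusted p = 2.14e-06, and adjusted p = 0.0559 with an estimated correlation), with Gata4 at least 65.9-fold lower. Biliary genes were lower in 11 of 22 cases and higher in 4 (adjusted p = 0.000986, and adjusted p = 0.420 with an estimated correlation), and hepatocyte genes lower in 5 of 8 (adjusted p = 0.00907, and adjusted p = 0.143 with an estimated correlation). The WNT and Notch list had 15 of 23 members lower and 5 higher (adjusted p = 0.0105, and adjusted p = 0.420 with an estimated correlation), with the ligand Wnt5a at least 186-fold higher and the stem cell receptor Lgr5 157-fold lower with a counting interval of 53.6 to 759. Mesenchymal genes were higher in 15 of 28 cases and lower in 1 (adjusted p = 0.000415, and adjusted p = 0.553 with an estimated correlation), with Postn at least 894-fold higher.

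Mitotic genes were lower in KPCh972-RR than in KPCh993-RR in 18 of 24 cases and higher in none, by a median of -0.40 (adjusted p = 0.00234, and adjusted p = 0.875 with an estimated correlation), led by Cenpf with -1.32. Autophagy and lysosome genes were higher in 14 of 28 cases and lower in 2 (adjusted p = 0.008, and adjusted p = 0.420 with an estimated correlation), and genes of the mitochondrial genome higher in 7 of 11 (adjusted p = 0.0183, and adjusted p = 0.875 with an estimated correlation). With the replicate block 3 further lists passed: ATF4 and the unfolded protein response (adjusted p = 0.101 without and 0.0127 with the block), NRF2 targets (0.0587 and 0.0272) and oxidative phosphorylation (0.0835 and 0.0214). MAPK output genes were lower in 7 of 20 cases and higher in 2 (adjusted p = 0.217), and without KPCh972-RR replicate 1 lower in 16 and higher in 2, by a median of -2.04 (adjusted p = 5.16e-09). Without that replicate 14 lists passed in place of 9. Dusp6 (-1.44, adjusted p = 0.00964) was lower in KPCh972-RR, a call that ended with the 6 libraries compared fitted alone (adjusted p = 0.0802). Etv4 (-1.68, adjusted p = 0.0728) passed with the replicate block (adjusted p = 0.0379) and without replicate 1 of KPCh972-RR (8.27e-08). It also passed with limma-voom (-2.69, adjusted p = 0.0031) and without the low-count filter (1.52e-34). Nras (0.22, adjusted p = 0.0543) passed with the block (0.0343), with DESeq2 (0.0314) and without replicate 3 of KPCh993-RR (0.0185). Further passes for Nras were with RLE (0.0475) and upper-quartile scaling (0.0262), the stricter filter (0.0302), limma-voom (0.0404) and halved counts (0.0386). Spry4 (-1.10, adjusted p = 0.396) and Egfr (0.59, 0.101) passed without replicate 1 of KPCh972-RR (5.18e-07 and 0.000507). With all libraries both passed without the low-count filter (8.08e-09 and 3.59e-05), and Spry4 passed with limma-voom (-3.00, adjusted p = 0.0161). Hras, Ppia, Trp53, Yap1 and Vim did not pass (adjusted p from 0.578 to 0.708). The largest differences were higher Igfbp2, Postn, Bhlhb9, Kcnip1, Slc6a15 and Alkal1 and lower Pilra, Crisp1, Acan, Dhrs4, Tns4 and Pax5 in KPCh972-RR.

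The comparison of the parental lines gave the baseline from which the resistant lines differed. hKP was the more mesenchymal parent: Vim was at 3799 ± 305 CPM in hKP and 1841 ± 234 CPM in KPCh, Acta2, smooth muscle actin, at 178 ± 39.9 against 0.0514 ± 0.0501 CPM, and Cdh1 at 142 ± 21.4 against 526 ± 51.5 CPM (SD, n = 3 each). The call for Cdh1 (adjusted p = 0.0315) ended when any 1 of the 6 libraries was left out (adjusted p from 0.0549 to 0.0969), and with DESeq2 (0.124), in a range from 2.28e-49 to 0.124 over 25 alternatives. Hras (0.45, adjusted p = 0.000826), Nras (0.32, 0.00784) and Yap1 (0.61, 0.000166) were higher in hKP, and Myc (-0.76, 0.00177), Egfr (-1.01, 0.00836) and Trp53 (-1.02, 8.85e-05) lower. Kras, Ppia, Spry4, Etv4 and Etv5 did not pass (adjusted p from 0.796 to 0.988), nor did Dusp6 (-0.46, adjusted p = 0.374). Dusp6 passed without KPCh972-RR replicate 1 (adjusted p = 0.0172) and without the low-count filter (adjusted p = 0.00525). With the 6 libraries compared fitted alone Dusp6 and Etv4 passed (adjusted p = 0.00236 and 0.0409). In all 7678 genes differed, 3790 higher and 3888 lower in hKP. Epithelial genes were lower in 18 of 24 cases and higher in none, by a median of -2.87 (adjusted p = 6.36e-10, and adjusted p = 0.0482 with an estimated correlation). Fibroblast markers were higher in 7 of 9 cases and lower in 1, by a median of 5.04 or 5.34 with 3 members set to the floor and 1 without a fold left out (adjusted p = 3.77e-07, and adjusted p = 0.0482 with an estimated correlation), with the growth factor receptor Pdgfrb at 115 ± 13.4 against 0.141 ± 0.0806 CPM. Of 28 mesenchymal genes 20 were higher and 3 lower (adjusted p = 9.56e-06, and adjusted p = 0.576 with an estimated correlation), and the mesenchymal factor Twist1, with 2 reads in hKP, was among the lower ones, 1610-fold lower with a counting interval of 289 to 63500. TGF-beta pathway genes were higher in 11 of 22 cases and lower in 2 (adjusted p = 0.00376, and adjusted p = 0.659 with an estimated correlation), with Bmp4 at 5.19. Biliary genes were lower in 10 of 22 cases and higher in 2 (adjusted p = 0.0125, and adjusted p = 0.659 with an estimated correlation). MHC class I genes were higher in 8 of 18 cases and lower in 1 (adjusted p = 0.0288, and adjusted p = 0.778 with an estimated correlation), and Psmb8 was at least 69.5-fold higher. Of 22 genes of cholesterol biosynthesis 10 were lower and none higher (adjusted p = 0.0359, and adjusted p = 0.778 with an estimated correlation). The largest differences were higher Actg2, Col3a1, Mgp, Xist, Angpt1 and Mgll and lower Evc2, Cdkn2b, Evc, Muc5ac, St8sia1 and Eif2s3y in hKP.

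The change of hKP117-RR was also tested against the mean change of the KPCh lines, here called the background difference. The hKP background had 1 resistant line, so a difference between backgrounds cannot be told apart from a difference between lines. KPCh972-RR and KPCh993-RR, which have the same parent, differed from each other for 7325 genes. The background difference passed for 6096 genes, with the change of hKP117-RR higher for 2970 and lower for 3126. The interferon list differed by a median of 2.44, with 16 of 28 members higher and 1 lower (adjusted p = 0.00166, and adjusted p = 0.827 with an estimated correlation). Oxidative phosphorylation differed by -0.37, with 15 of 25 members lower and 1 higher (adjusted p = 0.00107, and adjusted p = 0.827 with an estimated correlation). Without KPCh972-RR replicate 1 the number of lists that passed went from 2 to 6, and MAPK output was among them, with a median difference of 0.72 (adjusted p = 0.00697).

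Of 21 chromosome sets 4 passed in hKP117-RR, 7 in KPCh972-RR and 8 in KPCh993-RR against their parents. Chromosome 5 was higher in hKP117-RR, by a median of 0.47 over 1280 genes (adjusted p = 0.00209). It was lower in KPCh993-RR, by -0.43 (adjusted p = 0.00199), although the block at its start was higher. Chromosome 3 was higher in KPCh972-RR by 0.69 (adjusted p = 0.000493) and in KPCh993-RR by 0.45 (adjusted p = 0.000274), and both lines also had chromosome 8 higher (0.45 and 0.21) and chromosomes 12 (-0.35 and -0.43) and 17 (-0.37 and -0.49) lower. In hKP117-RR chromosomes 1 (-0.42) and 6 (-0.49) were lower and chromosome 15 (0.24) higher. KPCh972-RR further had chromosomes 2 (-0.29) and 15 (-0.27) lower, and KPCh993-RR chromosome 6 lower (-0.21) and chromosome 14 higher (0.23). In both of these lines the Y chromosome was the remaining set to pass, with 7 of 8 tested genes lower (adjusted p = 0.00176 and 3e-05). KPCh972-RR had chromosomes 3, 5, 8 and 17 higher and 2, 7, 11 and 15 lower than KPCh993-RR, and hKP had chromosomes 1, 3 and 7 higher and 5, 8, 19 and Y lower than KPCh. Y-linked genes were expressed in KPCh alone: Eif2s3y, Ddx3y, Kdm5d and Uty summed to 111.8 CPM in KPCh, and had 1 read in KPCh972-RR, 0 in KPCh993-RR, 2 in hKP117-RR and 0 in hKP. Xist, the RNA of the inactive X chromosome, was at 2807 ± 128 CPM in hKP, 2908 ± 558 in hKP117-RR, 0.421 ± 0.410 in KPCh, 4.11 ± 2.08 in KPCh972-RR and 0.175 ± 0.0610 in KPCh993-RR. These X-linked and Y-linked genes, apart from Eif2s3y, Ddx3y and Xist where the rule named them, were chosen after their values were seen.

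With the preset correlation 12, 12 and 9 of 40 lists passed in hKP117-RR, KPCh972-RR and KPCh993-RR against their parents, and 1 in each, the epithelial list, held with an estimated correlation. Adjusted over the list alone, more members of some lists passed: in hKP117-RR 21 MYC targets (18 over all genes) and 16 mesenchymal genes (14) were higher, in KPCh972-RR 16 gastrointestinal and squamous genes (14) were lower, and in KPCh993-RR 16 epithelial genes (15) were lower and 12 genes of oxidative phosphorylation (8) higher.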

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

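The tests of explanations and the counts of other splits in this part were chosen after the results they concern had been seen, while the tests of differences between backgrounds and lines were planned. The change of hKP117-RR was set against the mean change of the KPCh lines by a test of the difference itself. It differed for 6096 genes (32.5% of those tested) and 11 chromosome sets. It also differed for 31 of 58 genes named by the rule, which had been picked for their changes in the same data. It differed for the interferon list by 2.44 (adjusted p = 0.00166) and for oxidative phosphorylation by -0.37 (adjusted p = 0.00107), and both calls were lost with an estimated correlation (adjusted p = 0.827 each). Among single genes it differed for Nras by -0.55 (adjusted p = 0.00173), Egfr by -1.27 (0.0145), Trp53 by 1.07 (0.000747) and Cdh1 by -8.28 (0.000593), the last a fitted value that rests on few reads in hKP117-RR. The fall of Cdh1 was not particular to the hKP background. It fell in KPCh972-RR too and did not pass in KPCh993-RR, and those lines differed for it by -6.96 (adjusted p = 1.43e-05). For these 4 single genes the alternatives were not run on the background difference.

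KPCh972-RR and KPCh993-RR, set against each other, differed for 7325 genes (39% of those tested) and 8 chromosome sets. They also differed for 36 of the same 58 genes named by the rule. The lists that differed were epithelial by -4.27 (adjusted p = 5.14e-11), gastrointestinal and squamous by -5.18 (2.14e-06), mesenchymal by 1.2 (0.000415), biliary by -0.96 (0.000986), mitosis by -0.4 (0.00234), autophagy and lysosome by 0.49 (0.008), hepatocyte by -3.58 (0.00907), WNT and Notch by -1.93 (0.0105) and mitochondrially encoded by 0.69 (0.0183). With an estimated correlation the epithelial call held (adjusted p = 0.0281) and the others were lost, with adjusted p of 0.0559, 0.553, 0.42, 0.875, 0.42, 0.143, 0.42 and 0.875 in that order. The always-named genes that differed were Cdh1 by -6.96 (adjusted p = 1.43e-05), Dusp6 by -1.44 (0.00964), Myc by 0.49 (0.0268), Kras by 0.28 (0.0394) and Etv5 by -2.21 (0.046). The call for Kras held without hKP117-RR replicate 1, KPCh972-RR replicate 2 or KPCh993-RR replicate 3 and ended without any of the other 12 libraries (adjusted p from 0.0653 to 0.207, and from 0.021 to 0.207 over 25 alternatives). That for Etv5 held without KPCh972-RR replicate 1 and ended without any of the other 14 (0.0557 to 0.11, and from 2.69e-38 to 0.204 over 24 alternatives), and DESeq2 gave it no adjusted p. With the 6 libraries compared fitted alone the calls for Kras (0.156), Etv5 (0.204), Dusp6 (0.0802) and Myc (0.0666) ended. The call for Myc ended without KPCh972-RR replicate 2 (0.152) or KPCh993-RR replicate 3 (0.13).

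In the chromosome 5 block of KPCh993-RR, 24 of the 25 genes other than Abcb1a and Abcb1b at 5 CPM or more in KPCh were at least 2-fold higher. That count follows in part from how the block was drawn. Reads shared between Abcb1a and Abcb1b as the whole cause are argued against by the first part, which holds neither gene. There 25 neighbours in a row were at least 2-fold higher, against a longest run of 4 in 1000 shuffles of gene order. Library scaling is argued against by the next 20 genes, whose median was -0.49 against 3.09 in the first part of the block. For the first part 1 uniform gain in copies is a candidate explanation: over its 17 genes at 5 CPM or more in KPCh the SD of the log2 fold change was 0.22, against a median of 0.54 in windows of as many genes elsewhere, of which 260 of 10105 were lower (0.45 against 1.02 over its 30 genes at 1 CPM or more in KPCh or KPCh993-RR). For the second part, which holds the efflux pumps, the SD was 0.87 over 9 genes, against 0.43 elsewhere, where 8116 of 10265 windows were lower, and 0.91 against 0.82 over 14 genes, where 7269 of 13101 were, which is within the usual spread between genes that a gain leaves and so does not decide. DNA was not analysed here, so a gain, a change in regulation and any link to resistance stay open for both parts.

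MAPK output in KPCh972-RR replicate 1 was weighed next, and no biological explanation was tested. RNA of the parental line mixed into the library is argued against by genes nearly absent from replicates 2 and 3, which allow a median share of 0.07% (90th percentile 2.85%), while the MAPK output genes would need 94.6%. A library of another line under this label is argued against by a lowest correlation, of the log2 of CPM plus 1 over the tested genes, of 0.981 with its own replicates and a highest of 0.946 with another line. On the scale of log2 CPM used for the correlations between libraries these values were 0.9677 and 0.9185. Conditions at harvest, such as the presence of the drug, could differ between cultures, and the labels do not settle this.

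For the loss of epithelial and gain of mesenchymal genes, host mouse cells carried over from the animal may add mesenchymal RNA. In KPCh972-RR Xist, if host cells hold as much of it as hKP, allowed at most 0.22% of cells with 2 X chromosomes and the Y-linked genes 0.047% of cells with a Y, while epithelial genes kept a median of 0.93% of their level, which argues against host cells as the cause there. In hKP117-RR 14 of 17 genes at or under the floor in hKP stayed there, and host cells cannot be told apart from a change in the tumour cells by this test, since which of these genes host cells use is not known from these data. The epithelial list fell there by a median log2 fold change of -5.37 with members set to the floor. That argues against a small share of host cells as the cause of the epithelial loss. It does not exclude host cells as most of the culture, or as a source of mesenchymal RNA. The difference between parents and any effect of growth in the animal stay open, as untested.

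With 10 splits of 3 libraries against 3 no share under 0.05 can be had. For genes, 1 of 10 splits, the real one, gave as many calls as the real 7918 in hKP117-RR, 8426 in KPCh972-RR, 5106 in KPCh993-RR, 7325 in KPCh972-RR against KPCh993-RR and 7678 in hKP against KPCh, and the highest other count was 0 in each. For lists 4, 3, 8, 7 and 6 of 10 splits gave as many calls as the real 12, 12, 9, 9 and 7 in hKP117-RR, KPCh972-RR, KPCh993-RR, KPCh972-RR against KPCh993-RR and hKP against KPCh, and the highest others were 15, 14, 13, 14 and 12. For chromosome sets 1 of 10 splits reached the real 4, 7, 8, 8 and 7, with a highest other of 0. For genes changed the same way in all 3 resistant lines 1 of 100 assignments within the backgrounds reached the real 1192 (highest other 0), and for the difference between backgrounds 1 of 100 reached 6096 (highest other 4608). The other splits and assignments mix libraries of different lines within a group, so these shares do not show that chance is excluded. Each other split of 3 against 3 keeps part of the real difference and widens the spread within groups. The counts for lists therefore do not show either that the real calls are no better than chance.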

How the results depend on the processing

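Lists without KPCh972-RR replicate 1 and halved counts were chosen after seeing the data. No named gene reversed, and no list did under the alternatives where its direction was compared. With the estimated correlation and with fry the direction of a list was not compared, so a reversal could not be seen there. Of the genes called, the fold of 1 in hKP117-RR without hKP replicate 3, of 2 in KPCh972-RR against KPCh993-RR without KPCh972-RR replicate 1 and of 1 for the background difference without that replicate took the opposite sign, and 0 of these were called there. Of the counts of genes, lists and chromosome sets under an alternative, 209 stayed within 1.5 times the reported count and 28 did not. Values of named genes kept their side of the threshold in 22222 cases, lost the call in 563 and gained one in 57, and lists did so in 1505, 50 and 125. DESeq2 called 98.7, 99.0 and 98.7% of the genes called for hKP117-RR, KPCh972-RR and KPCh993-RR against their parents, with the same sign.

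A 2-fold threshold left 4011 genes in hKP117-RR, 4470 in KPCh972-RR, 2209 in KPCh993-RR and 505 shared by all 3, by construction. An estimated correlation left 1 list in each resistant line against its parent and in KPCh972-RR against KPCh993-RR, 2 in hKP against KPCh and 0 for the background difference. With fry 25, 24, 15, 24, 25 and 19 lists passed in that order of comparisons, and with its mixed form 37, 37, 36, 37, 39 and 38, since fry does not compare a list with other genes. Without KPCh972-RR replicate 1 the lists called went from 9 to 14 in KPCh972-RR against KPCh993-RR and from 2 to 6 for the background difference, and were 14, 15, 9 and 10 in hKP117-RR, KPCh972-RR, KPCh993-RR and hKP against KPCh. The chromosome sets called in KPCh972-RR against KPCh993-RR went from 8 to 5 with the preset correlation and to 5 with genes of at least 5 CPM. Genes of at least 5 CPM left 20 of 21 sets to test. The set left out was the Y chromosome, which had passed in KPCh972-RR and KPCh993-RR against KPCh. Against the parents the sets called then went from 7 to 5 in KPCh972-RR, from 8 to 6 in KPCh993-RR and from 4 to 5 in hKP117-RR. Apart from the removal of the Y chromosome, the cause was not tested for these.

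Leaving out 1 library gave 6590 to 8699 genes in hKP117-RR, 7338 to 8747 in KPCh972-RR, 3876 to 6014 in KPCh993-RR, 6164 to 7840 in KPCh972-RR against KPCh993-RR, 6492 to 8457 in hKP against KPCh, 900 to 1404 shared and 5211 to 6838 for the background difference, each highest without KPCh972-RR replicate 1. Where 2 libraries were left in a line, its spread was assumed to be that of the others in the common fit.

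With the replicate block, 8476 genes were called in hKP117-RR and 9004 in KPCh972-RR. In some comparisons not every same-numbered pair passed the limit of 0.1. Among these, the lists called went from 9 to 14 in KPCh993-RR and from 7 to 13 in hKP against KPCh. Correlations of same-numbered libraries ran from 0.0788 to 0.139 in hKP117-RR against hKP and from 0.0631 to 0.226 in KPCh993-RR against KPCh. In hKP against KPCh they ran from -0.0515 to 0.1455. Between KPCh993-RR and KPCh those of different numbers ran from -0.2025 to 0.0222, and each library matched its own number best. Over all lines 47 of 60 best matches shared the number. Correlations passed 0.1 in 16 of 30 same-numbered pairs and in 1 of 60 others. This points to something that libraries of the same number share, which the main fit leaves out. What it is was not tested. With the block the stem and progenitor list lost its call in hKP117-RR (adjusted p = 0.0667), while hypoxia (0.0418) and Hras (0.0464) passed there and Vim in KPCh993-RR (0.0256). Lists that gained a call in KPCh993-RR were ribosomal proteins (0.0132), mitosis, MYC targets and mitochondrially encoded (0.0177 each) and ATF4 (0.0314). In hKP against KPCh they were oxidative phosphorylation (0.0119), MYC targets (0.0137), E2F (0.0146), mitosis and mitochondrially encoded (0.0295 each) and fatty acid oxidation (0.0355). In the comparisons where every same-numbered pair passed that limit, the block changed no call of the always-named genes and lists beyond those given beside their results.

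Depth limits the folds of genes with no read in a group to lower bounds. Its effect on the calls was not tested.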

Other observations

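The tests in this part, runs of neighbouring genes, were chosen after the results had been seen. Beside the chromosome 5 block, 9 neighbouring protocadherin genes (Pcdhb16 to Pcdhgc3, chromosome 18, 37610867 to 37974926, GRCm39) were at least 2-fold higher in KPCh972-RR, by a median of 4.53, where the longest run in 1000 shuffles of gene order was 6. In hKP117-RR 8 genes from Lmo7 to Ndfip2 (chromosome 14, 101967386 to 105546732) were lower, by a median of -1.31, and 7 genes on chromosome 14 from 67910626 to 69933283 higher, by 1.5, where the longest run in shuffles was 6 for each.

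Of the lists without a call in any comparison, the lowest adjusted p over the 6 comparisons was 0.0558 for cell cycle inhibitors and p53 targets, 0.0587 for NRF2 targets, 0.0626 for cytosolic ribosomal proteins, 0.0628 for fatty acid oxidation, 0.0656 for hypoxia and 0.0713 for growth factor ligands. It was 0.118 for the RAF-MEK-ERK and PI3K-AKT cascade, 0.145 for drug efflux transporters, 0.16 for MAPK output and for apoptosis regulators, 0.18 for endothelial markers and 0.217 for RAS family and exchange factors. It was 0.251 for immune cell markers, 0.257 for housekeeping controls, 0.26 for YAP/TAZ targets, 0.29 for fatty acid synthesis and uptake, 0.302 for glycolysis and 0.412 for replication-dependent histones. These values are those of the main fit, and some of these lists passed under an alternative, as given above.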
